A study of Homo sapiens with 6 samples.

How the data were processed

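The series holds RNA-seq of human PC3 prostate cancer cells with a control shRNA (3 libraries) or an shRNA against TTC3 (3 libraries). Per the labels' protocols, ribosomal RNA was depleted from total RNA and strand-specific libraries were made, and the series design names an Illumina NextSeq instrument. Per the submitters' processing notes, Trim Galore, STAR, StringTie and the hg38 build were used. Tool versions, settings, the annotation release and whether counting used the strand are not given in the sources used here. The deposited tables hold an estimated count per gene and per transcript in each library, as whole numbers not scaled for library size. Gene and transcript totals were equal in all 6 libraries. Overlapping genes, antisense genes and near-identical copies are uncertain, since how reads were divided among them is not stated.

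Each library was assigned to its group and numbered from its title. All 62700 gene identifiers were found, with version, in a table of gene names. Positions, gene types and transcript sequences came from GENCODE 29 on GRCh38, the assembly also called hg38, which held 58207 of the genes and 98286 of the transcripts by identifier. Of the tested genes, 94.0% had a position and 92.3% a transcript length there. The TTC3 transcripts were matched by identifier.

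The estimated counts were whole and needed no rounding. They were tested with edgeR 4.0.16 in R 4.3.3. filterByExpr with default settings (counts of about 10 in a group and 15 in total) left 24325 genes and 53805 transcripts. Libraries were scaled by TMM factors of 0.924 to 1.05. A quasi-likelihood model (glmQLFit, glmQLFTest) was fitted over the 6 libraries without a block, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Fold changes are TTC3 shRNA relative to control shRNA, and the SE of a log2 fold change is its size divided by the square root of its F statistic. CPM values use the TMM-scaled library sizes. Libraries held 143246356 to 155526861 counts, so the spread between libraries limits precision for abundant genes and counting error adds to it for rare ones. A fold against a group without counts used a floor of 3 counts over the group, and a group with 1 to 3 counts was given a ratio with a 95% exact interval. Such intervals and floors cover counting error only.

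The gene lists, the tests, the rule for named genes and most of the alternative analyses were fixed before the data were examined. The 45 lists with at least 5 tested members covered signalling, proliferation, migration, stress, metabolism, RNA quality, cell identity and the TTC3 locus. They were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with its preset correlation of 0.01, adjusted over the lists. By rule, the named genes were TTC3, the 10 largest rises and 10 largest falls past the threshold with a symbol, a mean of at least 5 CPM and groups that did not overlap, up to 4 members per list in order of adjusted p (2 by expression where none passed), and the tested reported TTC3 partners. The text names fewer list members than the rule gives and marks genes chosen after their values were seen. Some genes that the rule gives are not reported here.

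Alternatives were DESeq2 size factors, library totals alone, scaling without mitochondrial genes and the 20 highest genes, DESeq2 1.42.0, limma-voom, no filter, at least 50 counts in 3 libraries, a test against a fold of 1.5 (glmTreat), an adjusted p of 0.01, the replicate number as a block, each library left out in turn, camera with estimated correlations, fry, and lists without shared members. Analyses for FPKM or TPM tables did not apply. Analyses chosen after seeing the data left out chromosomes 2 and 15, kept protein-coding genes alone, ran the lists with the scaling without mitochondrial and the 20 highest genes, or removed each library's trend (lowess, span 0.5) with transcript length, or with length and GC content. Trends were fitted on genes outside the lists with a mean of at least 5 CPM. Between replicates of a group, the median chi-square per gene was 3.85 to 30.2 times that of sampling noise. This ratio cannot tell separate cultures from repeated libraries, and each library was treated as a replicate. The first principal component of log2 CPM (61.3% of variance) separated the groups, and the second (14.3%) separated TTC3 shRNA replicate 1 from replicates 2 and 3 of that group.

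The procedure was tested on simulated data drawn from the libraries' means and sizes. Over 24325 simulated genes, 7.25% of edgeR calls and 33.8% of DESeq2 calls were unchanged genes. edgeR recovered 20.9% of 67 genes changed by 1.5-fold, 57.6% of 66 by 2-fold and 71.9% of 64 by 4-fold. Over 53805 simulated transcripts, edgeR recovered 0% of 65 changed by 4-fold, and 89.4% of DESeq2 calls were unchanged transcripts. Far fewer features were changed in these simulations than the 8165 genes and 2148 transcripts that edgeR called in the real libraries. The shares of unchanged calls and the recoveries need not hold there. Camera called the shifted list and 0 of the others. Simulated genes were drawn independently, while the estimated correlation within real lists reached 0.865 for small noncoding and polymerase III RNAs. False list calls that arise from such correlation were therefore not tested. With a simulated length trend and no other change over 22457 genes, 570 genes and 8 lists were called before its removal, and 1 gene and 0 lists after. The median log2 fold change of cytosolic ribosomal protein genes was 0.26 before and -0.01 after in that simulation. It imposed the same linear slope on every TTC3 shRNA library. The real slopes were -0.03, -0.17 and -0.22 per doubling of length in replicates 1, 2 and 3, so these counts and medians need not hold there. Further steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.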

Results

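RNA sequencing was carried out on PC3 cells, an established human prostate cancer line. The cells carried either a control short hairpin RNA (shRNA, an RNA that directs degradation of a matching messenger RNA) or an shRNA against TTC3, which encodes an E3 ubiquitin ligase reported to act on the kinase AKT. Each group held 3 libraries of total RNA depleted of ribosomal RNA. The deposited tables gave estimated counts for 62700 genes and 117688 transcripts. Gene counts summed to 143246356 to 154832203 per control library and 144655100 to 155526861 per TTC3 shRNA library, and 24325 genes were tested. The labels do not state that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

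The targeted gene was compared first. TTC3 (ENSG00000182670.14, protein-coding, hg38 chromosome 21, 37073226 to 37203112) was at 687 ± 7.86 CPM (counts scaled by library size) in control cells and 196 ± 27.5 CPM in TTC3 shRNA cells (SD, n = 3 each). The TTC3 shRNA mean was 28.6% of control. The estimated counts of TTC3 were 111423, 110463 and 101609 in control libraries and 34351, 25090 and 25550 in TTC3 shRNA libraries. On the log2 scale TTC3 fell by 1.81 ± 0.10 (SE, adjusted p = 5.65e-05, edgeR quasi-likelihood test) and was lower in 3 of 3 TTC3 shRNA libraries. The processed pseudogene TTC3P1, chosen after its values were seen, fell by 0.82 ± 0.11 (adjusted p = 0.00230). Reads shared between TTC3P1 and TTC3 make the level of each uncertain.

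TTC3 transcripts differed in how far their estimates fell. The 9 TTC3 transcripts in the table held at least 98.2% of the TTC3 gene count in each library. The protein-coding transcript ENST00000418766.6 (37073251 to 37165751) had the highest estimate in control cells, 388 ± 45.1 CPM, against 46.6 ± 19.96 CPM in TTC3 shRNA cells. It fell by 3.06 ± 0.36 on the log2 scale (SE, edgeR adjusted p = 0.0183). The protein-coding transcript ENST00000450533.6 also passed the test (log2 fold change -3.14 ± 0.53, adjusted p = 0.0413). The protein-coding transcript ENST00000399017.6 (37081596 to 37203112) was at 78.9 ± 9.17 and 61.4 ± 14.5 CPM, which did not pass (log2 fold change -0.36, adjusted p = 0.380). Isoforms share most of their sequence, so single estimates are uncertain, and differences between the transcripts were not tested. The count of 2 TTC3 transcripts past the test was 0 without any of the 3 control replicates or without TTC3 shRNA replicate 2, 1 without TTC3 shRNA replicate 3 and 3 without TTC3 shRNA replicate 1.

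**Figure D1:**
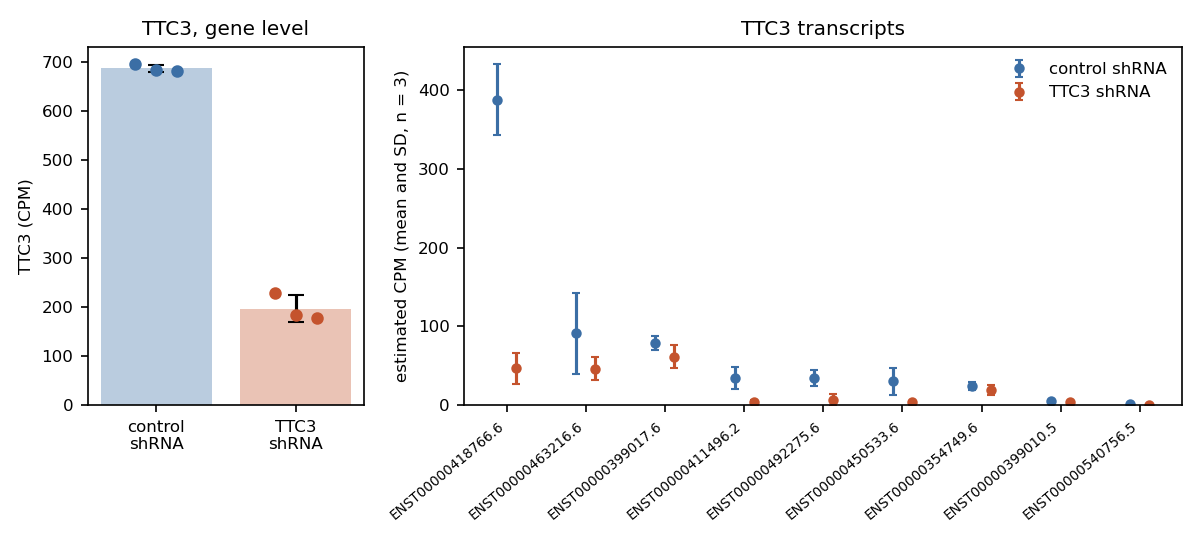
TTC3 in the 6 libraries. TTC3 gene counts, as CPM, have means of 687 in control and 196 in TTC3 shRNA libraries, and the 9 TTC3 transcripts (estimated CPM) are shown by group, with ENST00000418766.6 at 388 and 46.6. Bars or symbols are group means, whiskers are SD (n = 3 per group) and points on the bars are libraries.

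The 10 largest falls under the rule for named genes were as follows. TRPM2, a calcium-permeable channel, held 7346 counts over the control libraries and 3 over the TTC3 shRNA libraries, a ratio of 2242 (95% exact interval 767 to 10876). The proton-sensing receptor GPR65 was at 47.4 ± 1.63 and 0.0840 ± 0.0308 CPM, and GALC, the lysosomal galactosylceramidase, at 36.6 ± 1.11 and 0.0875 ± 0.0204 CPM. The surface glycoprotein CEACAM6 fell by 8.98 ± 0.44 on the log2 scale (SE). Log2 fold changes were -7.20 ± 0.34 for the DNA sensor IFI16, -6.03 ± 0.22 for the potassium channel KCNK10, -5.53 ± 0.33 for the cobalamin carrier TCN1, -4.72 ± 0.22 for the nicotinamide methyltransferase NNMT, -4.57 ± 0.21 for the antiviral protein BST2 and -4.52 ± 0.17 for CAMK2N1.

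Among genes that rose, TAGLN3, a calponin family member, went from 0.889 ± 0.0934 to 20.4 ± 2.43 CPM. NUDT11 was 22-fold higher, the junctional adhesion molecule JAM3 20.7-fold, the cyclic AMP phosphodiesterase PDE4A 11.2-fold, the secreted VGF 7.68-fold, the proteoglycan ESM1 7.17-fold, the collagen chain COL5A1 7.09-fold, the GABA receptor subunit GABBR2 6.37-fold and the Notch ligand DLL4 5.53-fold. The syndecan SDC1 was the most abundant of the 10, at 113 ± 0.597 and 682 ± 72.4 CPM. These 10 largest rises and the 10 largest falls had edgeR adjusted p of at most 0.000352. In each the 3 TTC3 shRNA libraries lay on the same side of all controls, which the rule for named genes required. CEACAM6 and NUDT11 have close paralogs, so their levels are uncertain where reads were shared.

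In total 8165 genes passed the edgeR test at an adjusted p of 0.05, 3827 higher and 4338 lower in TTC3 shRNA cells. At least a 2-fold change was seen for 711 of the higher and 2080 of the lower genes. The 2 groups did not overlap for 12225 genes, 50.3% of those tested, where chance gives 10%. With scaling by library totals alone the median of all genes shifted by -0.13 on the log2 scale, and 2518 genes were higher and 5356 lower, so small changes are relative to that shift. The total was 4546, 4632 and 4633 genes without control replicates 1, 2 and 3, 13739 without TTC3 shRNA replicate 1 and 5372 without TTC3 shRNA replicate 2. The number of members past the test moved by over 1.5 times in 10, 11 and 11 of the 20 gene lists called without control replicates 1, 2 and 3, and in 3, 6 and 3 without TTC3 shRNA replicates 1, 2 and 3.

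Interferon-stimulated genes were lower as a group in TTC3 shRNA cells. Of 39 tested members 37 fell and 0 rose (38 lower and 0 higher adjusted over the list alone), with a median log2 fold change of -2.16. MX1, an antiviral GTPase, went from a mean of 171 to 24.7 ± 1.13 CPM (SD, n = 3). MX2 fell by 3.92 ± 0.09 on the log2 scale (SE), with IFI27 at -3.51 ± 0.11 and the oligoadenylate synthetase OAS3 at -1.91 ± 0.06. The list passed the camera test (adjusted p = 2.08e-21) and was the only one of the 45 lists that passed with an estimated correlation (adjusted p = 0.0141 with an estimated correlation). IFI35 and ISG20, chosen after their values were seen, did not pass (adjusted p = 0.0522 and 0.275).

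NF-kappaB and inflammatory genes were lower as well. Of 32 tested members 29 fell and 1 rose (29 lower and 1 higher adjusted over the list alone), with a median of -2.49 (camera adjusted p = 2.11e-15, adjusted p = 0.147 with an estimated correlation). The neutrophil chemokine CXCL8 went from 198 ± 2.24 to 10.4 ± 0.539 CPM. The adhesion receptor ICAM1 fell by 2.55 ± 0.07 on the log2 scale, with TNFAIP3, an inhibitor of NF-kappaB signalling, at -3.24 ± 0.10 and the chemokine CXCL1 at -2.602 ± 0.08. The cytokine IL11, chosen after its values were seen, rose by 3.30 ± 0.28. A member without counts in TTC3 shRNA cells left the median the same when placed at its bound of 3 counts over the group.

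**Figure D2:**
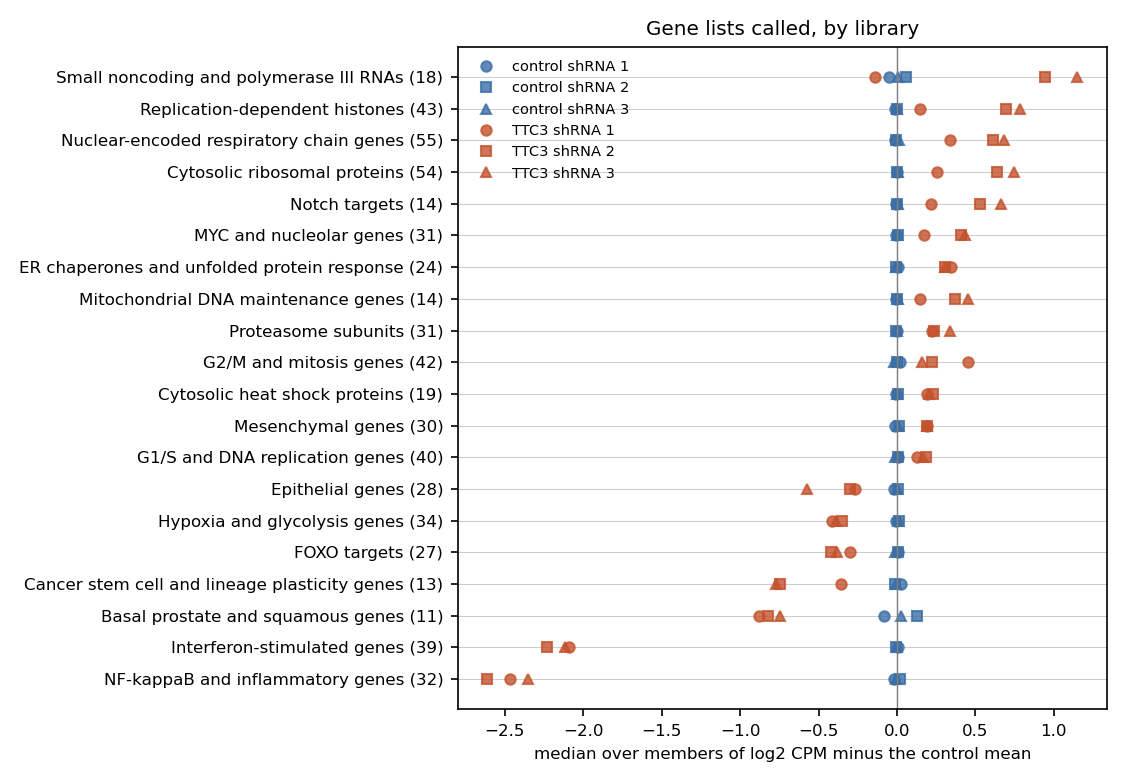
Gene lists called by the camera test, with the number of tested members. Each symbol is the median log2 CPM of a list's members in 1 library, relative to the control mean (x axis). NF-kappaB and inflammatory genes (median -2.49) and interferon-stimulated genes (-2.16) lie furthest below 0.

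Genes of protein synthesis and respiration were higher by smaller amounts. Cytosolic ribosomal proteins had 49 of 54 members higher and 0 lower (50 higher and 0 lower adjusted over the list alone), with a median of 0.56 (camera adjusted p = 4.27e-12, adjusted p = 0.427 with an estimated correlation). RPS7 rose by 0.69 ± 0.07 and RPL7 by 0.53 ± 0.06 on the log2 scale. Nuclear-encoded respiratory chain genes had 44 of 55 members higher and 1 lower (48 higher and 1 lower adjusted over the list alone), with a median of 0.58 (camera adjusted p = 5.80e-12, adjusted p = 0.250 with an estimated correlation). NDUFA10 of complex I rose by 0.72 ± 0.06 and SDHD of complex II by 0.65 ± 0.06. MYC and nucleolar genes had 21 of 31 members higher and 0 lower (25 higher and 0 lower adjusted over the list alone), with a median of 0.39 (camera adjusted p = 1.07e-07, adjusted p = 0.370 with an estimated correlation). Their median was 0.17, 0.41 and 0.43 in TTC3 shRNA replicates 1, 2 and 3. In that list ODC1, the first enzyme of polyamine synthesis, went from 566 ± 6.90 to 1479.7 ± 93.0 CPM. Proteasome subunits had 18 of 31 members higher and 1 lower (21 higher and 1 lower adjusted over the list alone), with a median of 0.28 (camera adjusted p = 1.18e-05, adjusted p = 0.111 with an estimated correlation), and PSMD2 rose by 0.66 ± 0.06. Ribosomal protein genes have many processed pseudogenes, so single values are uncertain.

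RNA composition also differed among the libraries. Signal recognition particle, 7SK and related small RNAs took 7.35% ± 0.363 of counts in control libraries (SD, n = 3) and 5.96%, 10.5% and 12.5% in TTC3 shRNA replicates 1, 2 and 3. Mitochondrially encoded genes took 5.45% ± 0.138 in control libraries and 6.29%, 3.73% and 3.54% in the same TTC3 shRNA replicates. Over 9881 protein-coding genes outside the lists, log2 CPM relative to control changed by -0.03, -0.17 and -0.22 per doubling of transcript length in TTC3 shRNA replicates 1, 2 and 3. Median transcript lengths were 975 bases for ribosomal protein genes and 929 bases for respiratory chain genes. The ribosomal protein median was 0.26, 0.64 and 0.74 in TTC3 shRNA replicates 1, 2 and 3, and the respiratory chain median 0.34, 0.61 and 0.68. With the length trend removed, an analysis chosen after seeing the data, both medians were 0.26. Removal shifted the median of all genes by -0.11 and left 3075 genes higher and 4864 lower. Small noncoding and polymerase III RNAs had 6 of 18 members higher and 0 lower (7 higher and 0 lower adjusted over the list alone), with a median of 0.83 (camera adjusted p = 0.00220, adjusted p = 0.547 with an estimated correlation). Their median was -0.14, 0.94 and 1.15 in TTC3 shRNA replicates 1, 2 and 3, and the call ended with fry (adjusted p = 0.114), with the length trend removed (adjusted p = 0.0957) and with both trends removed (adjusted p = 0.358), within a range of 2.47e-06 to 0.547 over its alternatives.

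**Figure D3:**
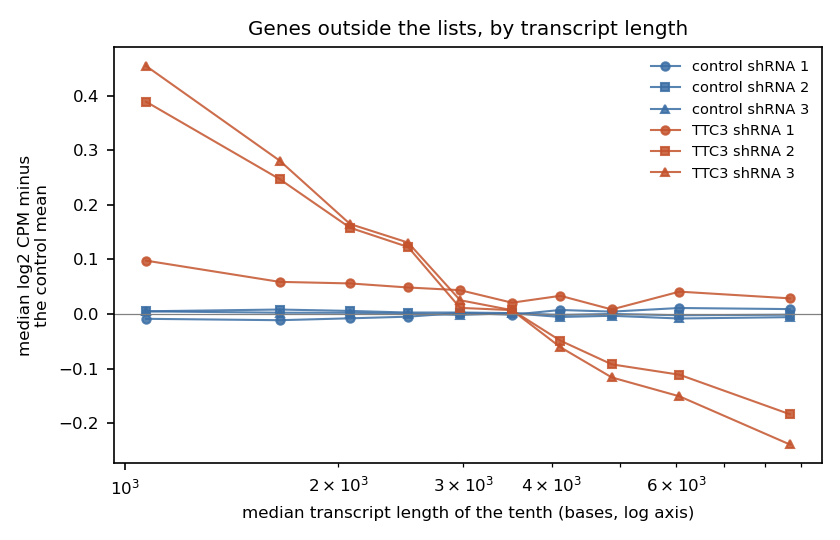
Expression by transcript length. Protein-coding genes outside the lists were divided into 10 bins by transcript length (x axis, bases, log axis), and each point is a bin's median log2 CPM relative to the control mean in 1 library. TTC3 shRNA replicates 2 and 3 go from 0.39 and 0.45 in the shortest bin to -0.18 and -0.24 in the longest, and replicate 1 from 0.10 to 0.03.

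Mitotic, replication and chaperone genes were higher in TTC3 shRNA cells. G2/M and mitosis genes had 20 of 42 members higher and 1 lower (22 higher and 1 lower adjusted over the list alone), with a median of 0.25 (camera adjusted p = 4.47e-06, adjusted p = 0.340 with an estimated correlation). Their median was 0.45, 0.22 and 0.16 in TTC3 shRNA replicates 1, 2 and 3, with the largest rise in replicate 1, and the list passed without that replicate (adjusted p = 0.00110, range 1.65e-11 to 0.340 over its alternatives). The centromeric histone CENPA rose by 1.12 ± 0.08 on the log2 scale, the mitotic kinase PLK1 by 0.95 ± 0.07 and the anaphase activator CDC20 by 0.92 ± 0.07. G1/S and DNA replication genes had 15 of 40 members higher and 1 lower (16 higher and 1 lower adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.000853, adjusted p = 0.147 with an estimated correlation). GINS4 rose by 0.78 ± 0.06 and MCM6 by 0.57 ± 0.05. Replication-dependent histones had 22 of 43 members higher and 3 lower (27 higher and 3 lower adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.000285, adjusted p = 0.523 with an estimated correlation). Their median was 0.15, 0.70 and 0.79 in TTC3 shRNA replicates 1, 2 and 3, and histone copies are near-identical, so H2BC7 at 0.66 ± 0.09 and H3C12 at -1.54 ± 0.16 are uncertain. The histone call ended with fry (adjusted p = 0.114) and with both trends removed (adjusted p = 0.238), within a range of 2.89e-07 to 0.523 over its alternatives, and median transcript length was 488 bases. ER chaperones and unfolded protein response genes had 13 of 24 members higher and 3 lower (13 higher and 3 lower adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.00253, adjusted p = 0.150 with an estimated correlation). The disulfide isomerases PDIA6 and PDIA4 rose by 0.90 ± 0.06 and 0.94 ± 0.08, and the stress sensor ERN1 fell by 0.94 ± 0.07. Cytosolic heat shock proteins had 10 of 19 members higher and 1 lower (11 higher and 1 lower adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.00266, adjusted p = 0.250 with an estimated correlation), and the co-chaperone BAG3 went from 129 ± 2.77 to 426 ± 38.9 CPM. Mitochondrial DNA maintenance genes had 6 of 14 members higher and 2 lower (8 higher and 2 lower adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0250, adjusted p = 0.461 with an estimated correlation), and TOP1MT rose by 0.74 ± 0.08. Their median was 0.15, 0.37 and 0.45 in TTC3 shRNA replicates 1, 2 and 3, and the call ended with at least 50 counts in 3 libraries (adjusted p = 0.0504, range 0.00569 to 0.461 over its alternatives).

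The epithelial list shifted lower and the mesenchymal list higher, with calls that depended on the setting. Epithelial genes had 11 of 28 members lower and 4 higher (12 lower and 5 higher adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.0346, adjusted p = 0.250 with an estimated correlation). Their median was -0.27, -0.30 and -0.58 in TTC3 shRNA replicates 1, 2 and 3. The tight junction claudin CLDN1 went from 73.5 ± 0.956 to 8.24 ± 1.33 CPM, the desmosomal protein DSP fell by 3.597 ± 0.14 on the log2 scale and the transcription factor ELF3 fell by 3.56 ± 0.21. The epithelial call ended without control replicate 3 (adjusted p = 0.0715), without TTC3 shRNA replicate 1 (adjusted p = 0.289) and with at least 50 counts in 3 libraries (adjusted p = 0.0511). In analyses chosen after seeing the data it ended with the length trend removed (adjusted p = 0.0957) and without chromosomes 2 and 15 (adjusted p = 0.0593), within a range of 0.000128 to 0.289 over its alternatives. Mesenchymal genes had 11 of 30 members higher and 5 lower (12 higher and 6 lower adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.0307, adjusted p = 0.250 with an estimated correlation). Fibronectin, FN1, went from 764 ± 8.79 to 3454 ± 459 CPM and COL6A3 rose by 2.20 ± 0.08, while the collagen cross-linking enzyme LOX fell by 2.67 ± 0.11. The mesenchymal call ended with at least 50 counts in 3 libraries (adjusted p = 0.0701) and, in analyses chosen after seeing the data, without chromosomes 2 and 15 (adjusted p = 0.0613) and with protein-coding genes alone (adjusted p = 0.0655), within a range of 0.000318 to 0.250 over its alternatives.

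Basal and lineage plasticity lists shifted lower. Basal prostate and squamous genes had 6 of 11 tested members lower and 1 higher (6 lower and 1 higher adjusted over the list alone), with a median of -0.90 (camera adjusted p = 0.00266, adjusted p = 0.250 with an estimated correlation). The list holds 19 genes, and those not tested had too few counts, so its shift covers only part of the list. The lineage factor TP63 was at 0.676 ± 0.0641 and 0.0136 ± 0.0118 CPM. Cancer stem cell and lineage plasticity genes had 8 of 13 members lower and 1 higher (9 lower and 1 higher adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.00266, adjusted p = 0.250 with an estimated correlation). The plasticity median was -0.35, -0.74 and -0.77 in TTC3 shRNA replicates 1, 2 and 3. The surface protein CD24 went from 85.1 ± 3.26 to 8.97 ± 1.61 CPM and the transcription factor KLF4 fell by 1.35 ± 0.08 on the log2 scale. Luminal prostate genes had 6 of 14 members lower and 1 higher (6 lower and 1 higher adjusted over the list alone) and did not pass as a list (camera adjusted p = 0.0990). TMPRSS2 fell by 1.04 ± 0.06, with the retinaldehyde dehydrogenase ALDH1A3 at -0.86 ± 0.06 and NDRG1 at -0.92 ± 0.07. Notch targets had 8 of 14 members higher and 1 lower (9 higher and 2 lower adjusted over the list alone), with a median of 0.44 (camera adjusted p = 0.00646, adjusted p = 0.370 with an estimated correlation), and HEY1 rose by 0.86 ± 0.09. The Notch median was 0.22, 0.53 and 0.67 in TTC3 shRNA replicates 1, 2 and 3. The basal, plasticity, hypoxia and neuroendocrine lists each hold a gene without counts in a group, and its bound gave the same medians.

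FOXO targets had 18 of 27 members lower and 1 higher (20 lower and 2 higher adjusted over the list alone), with a median of -0.38 (camera adjusted p = 2.89e-05, adjusted p = 0.111 with an estimated correlation). TXNIP, a thioredoxin-binding arrestin, went from 209 ± 1.80 to 64.0 ± 3.87 CPM. The kinase PDK4 fell by 2.94 ± 0.15 on the log2 scale, with the cell cycle inhibitor CDKN1B at -1.10 ± 0.08 and the mitochondrial dismutase SOD2 at -0.84 ± 0.06. Hypoxia and glycolysis genes had 16 of 34 members lower and 1 higher (19 lower and 1 higher adjusted over the list alone), with a median of -0.33 (camera adjusted p = 7.03e-05, adjusted p = 0.296 with an estimated correlation). The glucose transporter SLC2A1 fell by 1.71 ± 0.06, with the peptide hormone ADM at -3.03 ± 0.17 and the angiogenic factor VEGFA at -1.27 ± 0.07.

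Reported TTC3 partners and substrates had 6 of 13 members higher and 2 lower (8 higher and 2 lower adjusted over the list alone) and did not pass as a list (camera adjusted p = 0.109). The list passed with no filter on low counts (adjusted p = 0.0389), with fry (0.000481), and, in analyses chosen after seeing the data, with the length trend (0.0434) or both trends (0.00995) removed, within a range of 0.000481 to 0.338 over its alternatives. CIT, a kinase of cytokinesis, rose by 0.46 ± 0.06 on the log2 scale, ROCK2 by 0.79 ± 0.10 and RHOA by 0.41 ± 0.07, while POLG, the mitochondrial DNA polymerase, fell by 0.62 ± 0.12. ROCK2 lies on chromosome 2 and POLG on chromosome 15 from 45 Mb, whose genes shifted in the same directions. AKT2 rose by 0.30 ± 0.06 (adjusted p = 0.0119), FZR1 by 0.52 ± 0.13 (0.0221), and ROCK1 fell by 0.24 ± 0.06 (0.0235). Those 3 calls ended without control replicates 1, 2 and 3 in turn, with adjusted p of 0.0617, 0.0603 and 0.0685 for AKT2, 0.0856, 0.0724 and 0.0776 for FZR1, and 0.107, 0.101 and 0.0838 for ROCK1. FZR1 and ROCK1 also missed the threshold without TTC3 shRNA replicate 2 (adjusted p = 0.0786 and 0.0841) and replicate 3 (0.0579 and 0.0688), AKT2 with library totals alone (0.0807), RHOA and ROCK1 with the length trend removed (0.0551 and 0.132), and ROCK1 with both trends removed (log2 fold change -0.05). AKT1 was at 178 ± 2.92 CPM in control and 216 ± 28.6 CPM in TTC3 shRNA cells, which did not pass (log2 fold change 0.28 ± 0.10, adjusted p = 0.0729). SMURF2, UBE2D1 and UBE2D2, at -0.21 ± 0.10, -0.29 ± 0.15 and 0.16 ± 0.06, did not pass either (adjusted p = 0.150, 0.168 and 0.0868), nor did UBE2D3 at 0.10 ± 0.09 (0.469). Without TTC3 shRNA replicate 1, AKT1, SMURF2, UBE2D1 and UBE2D2 passed (adjusted p = 3.00e-05, 0.000189, 0.000193 and 0.00671). AKT1 also passed with DESeq2 (adjusted p = 0.0361), and SMURF2, UBE2D2 and UBE2D3 with both trends removed (adjusted p = 0.0388, 0.0122 and 0.00612). The UBE2D genes are close paralogs, so their levels are uncertain. AKT and mTORC1 components had 7 of 27 members higher and 7 lower (9 higher and 7 lower adjusted over the list alone), with the phosphatase INPP4B at -2.054 ± 0.26 and no call as a list (camera adjusted p = 0.568).

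The following lists did not pass the camera test but held members that changed in both directions. SRF and actin cytoskeleton genes had 15 of 35 members higher and 7 lower (15 higher and 7 lower adjusted over the list alone), with FLNC at 1.92 ± 0.09 on the log2 scale, and the list passed without TTC3 shRNA replicate 1 (adjusted p = 0.00964), with no filter on low counts (0.0144) and, in analyses chosen after seeing the data, without chromosomes 2 and 15 (0.0347) and with the length trend removed (0.0264), within a range of 0.00964 to 0.578 over its alternatives. TGF-beta and SMAD targets had 10 of 30 members higher and 12 lower (10 higher and 13 lower adjusted over the list alone), with THBS1 at -2.04 ± 0.07. YAP and TEAD targets had 10 of 22 members lower and 4 higher (10 lower and 4 higher adjusted over the list alone), with CCN1 at -2.04 ± 0.06. Integrins and laminins had 10 of 25 members lower and 6 higher (11 lower and 7 higher adjusted over the list alone), with ITGB8 at -2.17 ± 0.10. Matrix metalloproteases and protease regulators had 7 of 24 members lower and 6 higher (9 lower and 6 higher adjusted over the list alone), with MMP13 at -2.25 ± 0.09. EGFR and ERBB ligands and MAPK feedback genes had 12 of 30 members lower and 5 higher (13 lower and 5 higher adjusted over the list alone), with TGFA at -2.62 ± 0.10. WNT targets had 7 of 20 members lower and 3 higher (8 lower and 4 higher adjusted over the list alone), with RNF43 at -5.59 ± 0.15. ATF4 and amino acid response genes had 11 of 30 members lower and 5 higher (12 lower and 6 higher adjusted over the list alone), with STC2 at -2.054 ± 0.06. CDK inhibitors and senescence genes, a list shared in part with the inflammatory genes, had 8 of 16 members lower and 5 higher (8 lower and 6 higher adjusted over the list alone). Apoptosis regulators had 10 of 29 members higher and 9 lower (10 higher and 10 lower adjusted over the list alone), with BMF at -1.71 ± 0.10. p53 targets had 7 of 23 members lower and 5 higher (10 lower and 6 higher adjusted over the list alone), with TP53I3 at 1.11 ± 0.12 and PLK2 at -0.70 ± 0.08.

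The remaining lists did not pass either. NRF2 targets had 8 of 24 members higher and 8 lower (10 higher and 8 lower adjusted over the list alone), with TXNRD1 at -0.83 ± 0.07 on the log2 scale, a median of 0.10 and a mean of -0.18. Cholesterol and SREBP2 genes had 8 of 24 members higher and 5 lower (8 higher and 5 lower adjusted over the list alone). Fatty acid synthesis genes had 2 of 22 members higher and 2 lower (2 higher and 1 lower adjusted over the list alone), with LPIN1 at 0.66 ± 0.06. Autophagy and lysosome genes had 4 of 27 members higher and 3 lower (4 higher and 3 lower adjusted over the list alone), with GABARAPL1 at -1.29 ± 0.14, and their median of -0.00757 and mean of 0.0051 differed in sign. Mitochondrially encoded mRNAs had 2 of 13 members higher and 0 lower (2 higher and 0 lower adjusted over the list alone), with a median of -0.10 although the test ranked them toward higher values. Nuclear long noncoding RNAs had 5 of 13 members lower and 1 higher (5 lower and 2 higher adjusted over the list alone), with NEAT1 at -1.49 ± 0.06 and MALAT1 at -0.87 ± 0.07. Neuroendocrine and neuronal genes had 5 of 13 members lower and 1 higher (5 lower and 1 higher adjusted over the list alone), with FOXA2 at 2.16 ± 0.16. Fibroblast genes had 3 of 8 members higher and 1 lower (3 higher and 1 lower adjusted over the list alone), with PDGFRA at 1.68 ± 0.08. Leukocyte and endothelial genes had 3 of 7 members lower and 2 higher (4 lower and 2 higher adjusted over the list alone), with CD14 at 0.890 ± 0.0783 and 0.351 ± 0.0445 CPM. Chromosome 21 genes near TTC3 had 7 of 20 members higher and 7 lower (7 higher and 9 lower adjusted over the list alone), with ETS2 at -0.72 ± 0.06. Core housekeeping references had 6 of 15 members higher and 3 lower (6 higher and 3 lower adjusted over the list alone), with B2M at -1.01 ± 0.06. The 25 lists that did not pass had camera adjusted p from 0.0799 to 0.927. Medians of the AKT, NRF2, cholesterol, fatty acid and housekeeping lists changed sign with library totals alone.

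Several of the strongest falls were neighbours on chromosome 14. GALC (87837820 to 87993665), GPR65 (88005124 to 88014811) and KCNK10 (88180103 to 88326907, all hg38) kept 0.241%, 0.176% and 1.52% of the control level. HISLA, a noncoding gene between GPR65 and KCNK10, held 161 counts over control and 0 over TTC3 shRNA libraries, at least 49.1-fold lower against a floor of 3 counts over the group. The next protein-coding genes, SPATA7 and PTPN21, kept 69.3% and 59.6%. HISLA, SPATA7 and PTPN21 were chosen after their values were seen.

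Genes of chromosome 2 and of part of chromosome 15 also shifted, a comparison chosen after seeing the data. On chromosome 15 from 45 Mb, 230 protein-coding genes with a mean of at least 5 CPM had a median log2 fold change of -0.54 (quartiles -0.74 and -0.30), with 174 lower and 2 higher past the test. Before 45 Mb the shift was smaller, with 110 such genes at a median of -0.09, 31 lower and 11 higher. On chromosome 2, 711 such genes had a median of 0.33 (quartiles 0.08 and 0.60), with 383 higher and 56 lower. The medians of the other 21 chromosomes ran from -0.16 to 0.22. As a set, the tested genes of chromosome 15 passed the camera test (adjusted p = 1.42e-10, adjusted p = 0.0351 with an estimated correlation), and those of chromosome 2 passed at adjusted p = 3.92e-06 (adjusted p = 0.205 with an estimated correlation). Of the genes named in this text, SDC1, FN1, COL6A3, ODC1, RPS7, NDUFA10, CENPA, MCM6, PDIA6, ROCK2, TGFA, TP53I3 and LPIN1 lie on chromosome 2, POLG, ALDH1A3 and ISG20 on chromosome 15 from 45 Mb, and B2M, DLL4, THBS1 and BMF before 45 Mb.

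**Figure D4:**
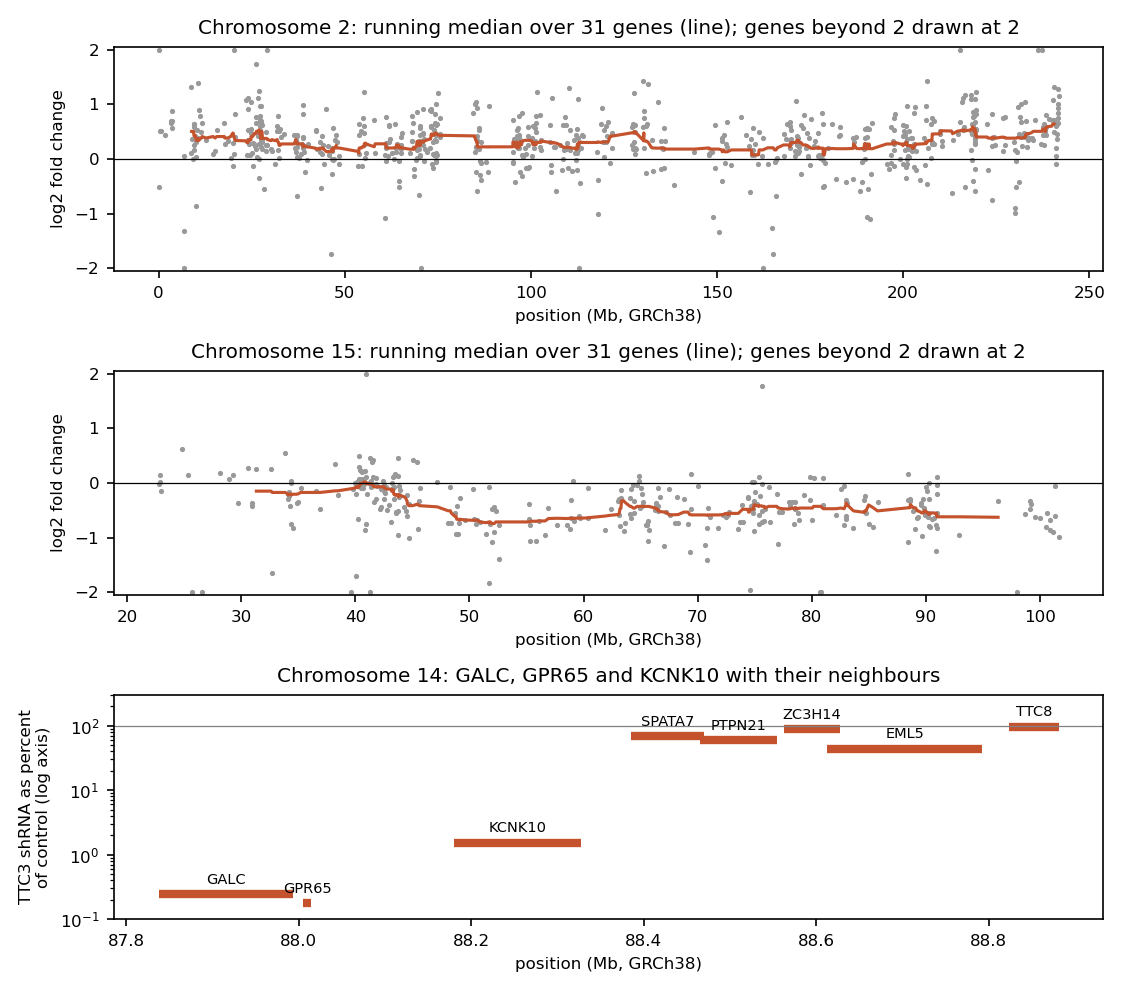
Changes by position. The panels of chromosomes 2 and 15 show the log2 fold change of protein-coding genes with a mean of at least 5 CPM by position (Mb, hg38), with a running median as a line and genes beyond 2 drawn at 2, and medians of 0.33 on chromosome 2 and -0.54 on chromosome 15 from 45 Mb. The chromosome 14 panel shows TTC3 shRNA levels as a percent of control (log axis) for protein-coding genes drawn over their length, with GALC at 0.241% and SPATA7 at 69.3%.

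At the transcript level, 749 transcripts were higher and 1399 lower among 53805 tested (edgeR). The total of 2148 was 6765 without TTC3 shRNA replicate 1, 391 and 517 without replicates 2 and 3 of that group, and 167 and 141 without control replicates 1 and 2. Without control replicate 3 it was 47 higher and 109 lower.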

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

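The tests without chromosomes 2 and 15, with protein-coding genes alone, with trends removed, and of lists without mitochondrial and the 20 highest genes in the scaling were chosen only after the results were seen. Calls of single genes were not compared under the fold of 1.5 or the adjusted p of 0.01. TTC3 kept its direction and call in each of the other analyses, with log2 fold changes of -1.93 to -1.68. Of the 199 other named genes, 170 kept their call under each of those other alternatives that tested them. The genes that changed sign numbered 2. UBE2D3 was at -0.02802 with library totals alone, and MT-ATP8, a short transcript, at -0.17 with the length trend removed and -0.00279 with both trends removed. The 8165 genes past the threshold became 2033 against a fold of 1.5 (466 higher, 1567 lower) and 4082 at an adjusted p of 0.01 (1688 higher, 2394 lower), both stricter by construction. Library totals alone gave 2518 higher genes, with a shift of all genes. Leaving out 1 library gave 4546 to 13739 genes (1835 to 6674 higher, 2711 to 7065 lower), 19 to 20 lists, 141 to 6765 transcripts and 0 to 3 lower TTC3 transcripts. In each of these counts the highest value came without TTC3 shRNA replicate 1, except for lists. Of the 20 lists called, 1 was called with estimated correlations, and fry, which does not compare a list with other genes, called 18 of them and 37 of the 45 lists in all. The estimated correlation was 0.601 for cytosolic ribosomal proteins. It lay under the preset 0.01 for the proteasome (-0.00172), FOXO (0.00148) and G1/S (0.00272) lists, whose calls were also lost. A call lost with estimated correlations therefore does not by itself show a high correlation within the list. DESeq2 called 9143 transcripts (5 of TTC3, lower), and no filter left 1159 (1 of TTC3), with more transcripts tested. The cause of the DESeq2 difference was not tested in these libraries. Camera calls were also lost with at least 50 counts in 3 libraries for the epithelial, mesenchymal and mitochondrial DNA maintenance lists (adjusted p = 0.0511, 0.0701 and 0.0504). Depth limits genes such as TP63, with few counts in TTC3 shRNA libraries.

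Replicate numbers did not pair the libraries. Deviations of same-numbered libraries correlated at 0.05, 0.04 and -0.00582, although replicates 1 and 2 of each group correlated best with their own number. With the replicate number as a block, 6929 genes, 18 lists, 0 transcripts and 0 TTC3 transcripts passed, with fewer residual degrees of freedom. The epithelial and mesenchymal calls ended with this block (adjusted p = 0.0666 and 0.0506), and so did that of ROCK1 (adjusted p = 0.0509).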

Other observations

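The tests of gene families, chromosomes, neighbouring genes, scalings, splits of the libraries and the length trend as the whole cause were chosen only after the results were seen. Gene families were taken from symbol stems with at least 10 tested members. The 4 families described here are a selection from many more that were tested. Others passed camera as well, such as GOLGA (adjusted p = 1.27e-06, and 0.655 with an estimated correlation). A stem was the symbol up to its first digit or hyphen, over all tested genes. A family can therefore count pseudogenes and noncoding genes with such symbols. Zinc finger genes (ZNF) had 219 of 544 members lower and 27 higher, with a median log2 fold change of -0.31 (camera adjusted p = 1.27e-06), and -0.29 with length and GC trends removed. Removal of both trends moved the median of all genes by -0.12, so relative to other genes the ZNF fall became smaller. The family still passed camera then (adjusted p = 0.000112). Axonemal dynein heavy chains (DNAH) had 8 of 12 lower and 0 higher, with a median of -1.26 (camera adjusted p = 0.000197). Mucins (MUC) had 12 of 18 lower and 2 higher (camera adjusted p = 0.0120), a call that ended with both trends removed (adjusted p = 0.0777). Large-subunit mitochondrial ribosomal proteins (MRPL) had 32 of 57 higher and 0 lower, with a median of 0.40 that was 0.20 with both trends removed. With estimated correlations these 4 families did not pass (adjusted p = 0.655 for ZNF, DNAH and MUC and 0.675 for MRPL).

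Ribosomal protein and respiratory chain genes have short transcripts, and short transcripts outside the lists were also higher in TTC3 shRNA replicates 2 and 3. With the length trend removed, the medians went from 0.56 to 0.26 for ribosomal proteins and from 0.58 to 0.26 for the respiratory chain, so a library trend may account for part of both rises. Both values lie under 0.5 times the first value, the bound set for this test, but removal also moved the median of all genes by -0.11, and without that shift the bound would not have been met, so the size of the part stays open. At the preset correlation the trend is argued against as the whole cause, since both lists still passed camera with the trend removed (adjusted p = 2.07e-08 and 1.20e-09). Neither list passed with an estimated correlation even with the trend kept (adjusted p = 0.427 and 0.250), so the argument holds for the preset correlation alone. It also covers the 2 lists and not each symbol family of such genes. With length and GC trends removed, RPS still passed camera (median 0.11, adjusted p = 0.0375). RPL (-0.02, 0.203), NDUFA (0.06, 0.174), NDUFB (0.34, 0.0799) and COX (0.19, 0.0913) no longer passed. Both lists kept their call at the preset correlation with both trends removed. The RPL and RPS stems held 239 and 129 tested members against 54 in the ribosomal protein list, so most of their members lie outside that list. Such families can hold pseudogenes. Whether the remaining rise reflects TTC3 knockdown stays open as untested.

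The fall of interferon-stimulated and inflammatory genes was weighed against trends and scaling. With length and GC trends removed the medians were -2.15 and -2.69, and their highest values under the other scalings were -2.15 and -2.48. This argues against the trends and the scalings run as the source of falls of this size. Library totals alone moved the median of all genes by -0.13 and removal of both trends by -0.12. Neither test therefore had much room to bring the medians near 0. A response to TTC3 loss, a response to the hairpin vectors and a difference between the cell populations stay open, since the data hold 1 TTC3 shRNA group and 1 control group.

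The chromosome shifts and the near-absent neighbours on chromosome 14 may reflect DNA differences between the cell populations rather than knockdown. On chromosome 15 from 45 Mb 92.6% of well expressed protein-coding genes were lower and on chromosome 2 81.3% higher, as copy number differences would give, with the segment start and bounds set after seeing the values. On the other chromosomes together 55.5% were higher and 44.5% lower, with up to 68.7% higher on chromosome 11 and 71.7% lower on chromosome 18. The shares follow from the shifts that prompted the comparison and are not separate evidence. Length and GC trends are argued against, since all tested genes of chromosomes 15 and 2 had medians of -0.54 and 0.20 with both trends removed. With the trends kept, the same genes had medians of -0.46 and 0.27, and removal moved the median of all genes by -0.12. The gene order tested held 16101 genes with a position and a mean of at least 0.5 CPM, which leaves out HISLA. In this order GALC, GPR65 and KCNK10 formed a run of 3 neighbours below a log2 fold change of -5. As long a run was found in 2 of 10000 random gene orders (permutation p = 0.0003, and 0.0002 below -6, the first of 2 thresholds, both set after seeing the values), which argues against chance placement. DNA was not measured, so a copy number difference stays a hypothesis.

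There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave 8165 genes, 20 lists and 2148 transcripts, and the highest values of the other splits were 1 gene, 12 lists and 4 transcripts, with 1 split as large as the real one in each case, the real one itself. Each of the other splits mixes the groups, so the real group difference enters its spread and holds down its gene calls. The splits therefore say little about chance.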
